A study of Hakea prostrata with 26 samples.

How the data were processed

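Total RNA from Hakea prostrata leaves and roots was prepared with a stranded total RNA kit after plant ribosomal RNA removal, per the labels' protocols. The deposited values are estimated counts per assembled transcript, with totals that differ between libraries. An estimated count need not be whole, and 30.2 to 59.5% of the values of a library were not. For the processing before the authors deposited the estimated counts, the submitters' processing notes name Trim Galore 0.6.6, kallisto without a version and DESeq2 1.30.1, with no role or order. The assembly and its version are not given in the sources used here. The trimming settings, strand handling and any filter before deposit are likewise not given. The IDs have the form of Trinity transcripts, with a gene and an isoform part, and 96 of the 51697 transcripts had 0 in every library. Isoforms of one gene share reads, so the estimate for a single isoform is uncertain wherever its gene has several.

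Groups were taken from the labels of the 26 libraries, which put 15 in wild leaf stages 1, 2, 3, 4 and M with 3 replicates each, and no library was left out. The white root libraries at 1 and 10 uM Pi had the same total after rounding, 11508234, while 90.9% of their values differed, and both were used. Estimated counts were rounded to whole numbers before all tests. Analyses used R 4.3.3, edgeR 4.0.16, limma 3.58.1 and, as an alternative tool, DESeq2 1.42.0. For the wild leaves, transcripts were kept with filterByExpr by stage (minimum count 10, minimum total 15), scaled by TMM and fitted with edgeR's robust quasi-likelihood model over all 15 libraries, with stage as the only factor and 10 residual degrees of freedom. The test of the 5 groups together and contrasts of stages 1 and 2, 2 and 3, 3 and 4, 4 and M, and 1 and 4 were adjusted by Benjamini-Hochberg, and an adjusted p under 0.05 counted as passing. Standard errors are the absolute log2 fold change over the square root of F.

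The 6 white root and mature leaf libraries were fitted with tissue and log10 Pi as terms, with 3 residual degrees of freedom, and a tissue by Pi term was tested in a further fit. Cluster root libraries had no replicate and were described by size: log2 CPM with a prior count of 2, transcripts with at least 100 counts in a library of the pair, and a 4-fold difference. Counts were given exact Poisson intervals at 95%. A fold against a group with 0 counts in all libraries is a lower bound against 3 counts over the group, and with 1 to 3 counts the ratio has an exact binomial interval. Such a bound falls by construction when a library of the group at 0 is left out, since a smaller total then stands behind the 3 counts. Medians given with bounds set such transcripts to their bound and leave out those with at most 3 counts in both groups. Where p-values are given, replicates of a wild leaf stage are taken as leaves of separate plants, as the labels' protocols describe them.

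The tests, covariates, alternatives and the rule for named transcripts were fixed before the data were examined. Named transcripts have the largest log2 fold change in each direction among those with an adjusted p under 0.05, a mean log2 CPM of at least 2 and group CPM ranges that do not overlap. For the cluster root they have the largest differences from day 0 to day 12. Since no ID is paired with a name, the first 2 in each direction are given. The 24 gene lists fixed in advance, which covered ribosomal proteins of the cytosol, mitochondria and plastids, photosynthesis, phosphate starvation and other processes, matched 0 IDs by name, so these lists and the question of a shift between kinds of ribosome were not analysed here. The lists from hydroponic libraries, the shares of single transcripts, counts summed per Trinity gene and libraries thinned to one total were chosen after the data had been seen. Lists were tested with limma's camera at a preset correlation of 0.01, with an estimated correlation and with the replicate number as a block, which compare a list with the other transcripts. A separate test, fry, asks whether a list moved on balance. All were adjusted over the 4 lists within a contrast.

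Replicate numbers were checked for pairing across stages. Deviations from stage means correlated at r = 0.117 to 0.393 in all 30 pairs of libraries with the same number and at -0.264 to -0.0151 in the 60 pairs with different numbers, and 15 of 15 libraries correlated best with their own number. The deviations of a stage sum to 0, so with positive values for the same number the others are negative on balance and are no separate evidence. From the values of the same-numbered pairs, the numbers were taken to pair the samples. The fit with the replicate number as a block was run beside the design fixed in advance, which had no block. Other alternatives were DESeq2 size factors, TMM without the 20 most abundant transcripts, no low count filter, a stricter filter (1 CPM in every library of a stage and 50 counts in total), DESeq2, a fit without robust estimation, fits of 2 stages alone, a test against a 1.5-fold change, each library left out in turn, Pi as a factor or on a linear scale, and for cluster roots other prior counts, library totals and a minimum of 20 counts.

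The tests were tried on simulated counts with the means and library sizes of the real data and 200 changed transcripts. In the contrast of stages 1 and 2, fitted on 29462 transcripts, 8.20% of 2-fold, 32.3% of 4-fold and 76.2% of 16-fold changes were recovered, and 3.90% of calls were false. In the contrast of stages 3 and 4, on 29119 transcripts, these were 6.15%, 27.7% and 70.3%, with 5.63% false. In the test over the 5 groups, on 29195 transcripts, they were 6.35%, 23.8% and 61.3%, with 5% false. In the hydroponic tissue test, on 33273 transcripts, 1.67% of 4-fold and 31.6% of 16-fold changes were recovered with 9.52% of 21 calls false. In the Pi test, on 33184 transcripts, simulated changes were set per unit of log10 Pi. Of changes of 4-fold and 16-fold per unit, 19.7% and 44.3% were recovered, with 4.88% of calls false. From the lowest to the highest Pi supply such changes are larger than 4-fold and 16-fold. These shares are therefore not those for 4-fold and 16-fold changes over the range of supply. With 200 changed transcripts, totals of 1517487 to 11418655 counts and 3 libraries per stage, most simulated 2-fold changes in the wild leaf tests were not recovered. In the real data far more transcripts passed, 14224 of 31067 over the 5 groups. Fewer changed transcripts make the Benjamini-Hochberg cutoff stricter, so the recovered shares are not those of the real wild leaf tests.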

Results

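RNA was sequenced from leaves and roots of Hakea prostrata, a shrub of the Proteaceae that grows on phosphorus-poor soils in south-western Australia. Leaves of plants growing in the field formed 5 groups of 3 libraries, stages 1, 2, 3 and 4 of leaf growth and a group labelled stage M, whose meaning the labels do not give. The labels say that a replicate of each stage was taken from the harvested plants and that the 3 with the best RNA were sequenced. Plants in hydroponics gave 11 further libraries with 1 library per condition. These were cluster roots, the dense clusters of short rootlets that release carboxylates and take up scarce phosphate, on days 0, 1, 4, 7 and 12, and white roots and mature leaves at 1, 10 and 50 uM phosphate (Pi). Total estimated counts ran from 4848372 to 6178864 at wild leaf stage 1, from 4520030 to 11418655 at stage 2, from 4859869 to 6044325 at stage 3, from 1517487 to 3004237 at stage 4 and from 2644973 to 4054878 at stage M. In hydroponics they ran from 8163081 to 10857613 in cluster roots, from 9486439 to 11508234 in white roots and from 17130939 to 20283815 in mature leaves. The values covered 51697 assembled transcripts, named by Trinity IDs of 25047 genes, 11687 of which had several isoforms. No ID is paired with a gene name or description, so transcripts are named by ID.

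The study compared expression over the stages of leaf growth. To describe the stages by kind of transcript, 2 lists were taken from the hydroponic libraries after the data had been seen, and their use over the wild leaf stages was likewise chosen then. Leaf-preferring transcripts (3963) were at least 4-fold higher in mature leaf than in white root and passed the test between these tissues, and root-preferring transcripts (5715) were at least 4-fold higher in white root. Of these, 3654 leaf-preferring and 3329 root-preferring transcripts were tested in the wild leaves, and the libraries that set the lists are not among the wild leaf libraries. The leaves that set the lists were mature, so the lists mix organ with leaf maturity and cannot tell them apart. Root-preferring transcripts are low in mature leaf and were tested only where the filter found them expressed in wild leaf. A fall of that list towards later stages is therefore partly built in.

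Expression differed over much of the measured transcriptome between the 5 wild leaf groups. Of 31067 tested transcripts, 14224 (45.8%) differed between the 5 groups in edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05. The means of these transcripts were most often highest at stage 1 or stage M: 4861 (34.2%) had their highest mean at stage 1 and 3947 (27.7%) at stage M, against 1510 at stage 2, 2081 at stage 3 and 1825 at stage 4. With stage M placed last, a rise at every step was seen in 2141 (15.1%) and a fall at every step in 2083 (14.6%). A random order of the 5 means would give 0.833% for each. These transcripts were selected for differing between the same groups, so that share is not their chance level. When the isoforms of a gene were summed, 11329 of 16668 genes differed. The first principal component of log2 CPM (counts scaled to a common library size), with 47.0% of the variance, ordered the stage groups from 1 to M, with the second at 12.01%. Replicates correlated less at stage 4 (r = 0.775 to 0.803 across transcripts) than in the other groups (0.847 to 0.900).

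**Figure D1:**
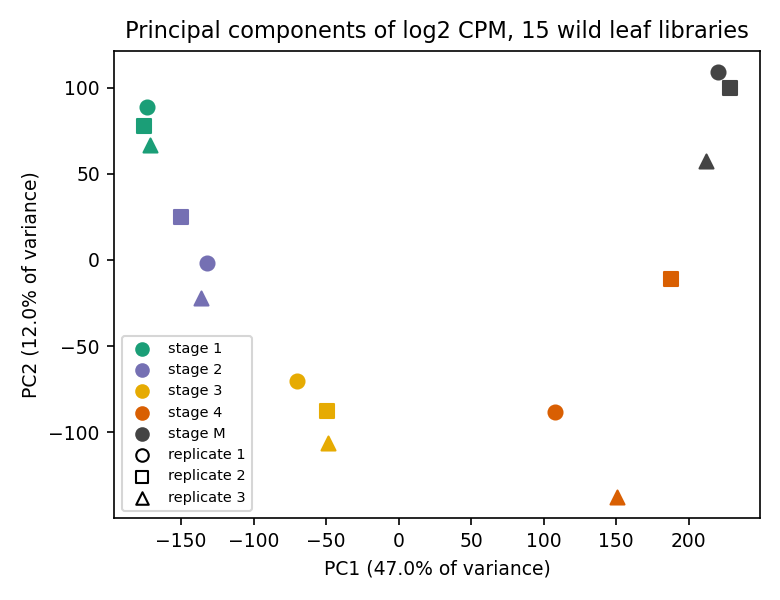
Principal components of log2 CPM in the 15 wild leaf libraries, with PC1 (47.0% of the variance) on the horizontal axis and PC2 (12.01%) on the vertical axis; colours mark stages and symbols mark replicate numbers. The libraries run from stage 1 on the left to stage M on the right, and the 3 stage 4 libraries lie farther apart than those of the other groups.

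From stage 1 to stage 2, more leaf-preferring transcripts rose than fell. Over all transcripts rises also outnumbered falls, by a margin that differed between fits. Of 680 transcripts that passed (2.19% of those tested), 495 rose and 185 fell, with median log2 fold changes of 1.74 and -1.35. Among the leaf-preferring transcripts 266 rose, 9 fell and 3379 did not pass the test, with a median log2 fold change of 0.40 (0.41 with transcripts at 0 in a group set to their bound; limma's camera, adjusted p = 1.96e-16, and 0.0106 with an estimated correlation). Among the root-preferring transcripts 17 rose, 68 fell and 3244 did not pass (median -0.12 with and without bounds; camera, adjusted p = 0.000273, and 0.0205 with an estimated correlation). TRINITY_DN5984_c0_g1_i3 was at 0 in all stage 1 libraries and at 8.98 ± 7.01 CPM (SD, n = 3) at stage 2, at least 62.6-fold higher (39.8-fold or 40.4-fold without stage 1 replicate 2 or 3; edgeR, adjusted p = 0.00222), and its gene rose by a log2 fold change of 9.25. TRINITY_DN9265_c0_g1_i42 rose from 0 to 7.64 ± 5.02 CPM, at least 70.1-fold (36.6-fold without stage 2 replicate 1, and 44.6-fold or 45.3-fold without stage 1 replicate 2 or 3; edgeR, adjusted p = 0.00222), and its gene by 2.16. TRINITY_DN55853_c0_g3_i1, a gene with a single isoform in the data, fell from 372 ± 67.5 to 42.0 ± 20.2 CPM (log2 fold change -3.15, SE 0.38; edgeR, adjusted p = 0.00120). TRINITY_DN1429_c0_g1_i13 fell from 18.6 ± 4.09 to 1.61 ± 0.485 CPM (log2 fold change -3.47, SE 0.41; edgeR, adjusted p = 0.00120), and its gene by -3.48. The count of 680 was 236, 236 or 229 without stage 1 replicate 1, 2 or 3, 189 or 276 without stage 2 replicate 1 or 3, and 1120 without stage 4 replicate 2, a library of neither stage. It was 1092 with the replicate number as a block (68.7% rising against 72.8%), 2405 with DESeq2 (55.1%) and 1891 in a fit of these 2 stages alone (52.0%; 984 rose and 907 fell). It was 207 in a test against a 1.5-fold change (85.5%) and 1484 for summed genes (57.3%; 850 and 634).

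From stage 2 to stage 3, leaf-preferring transcripts again rose more often than they fell, and the falls among all transcripts were larger than the rises. Of 1447 transcripts that passed (4.66%), 823 rose and 624 fell, with median log2 fold changes of 1.32 and -2.26 (-2.25 with bounds), and of those that changed at least 4-fold 221 rose and 341 fell. Among the leaf-preferring transcripts 496 rose, 21 fell and 3137 did not pass (median 0.47, 0.48 with bounds; camera, adjusted p = 3.27e-22, and 0.00320 with an estimated correlation). Among the root-preferring transcripts 15 rose, 246 fell and 3068 did not pass (median -0.29 with and without bounds; camera, adjusted p = 1.27e-07, and 0.00320 with an estimated correlation). TRINITY_DN1653_c0_g1_i29 rose from 0 to 4.38 ± 0.401 CPM (SD, n = 3), at least 41.9-fold (21.0-fold without stage 2 replicate 1; edgeR, adjusted p = 0.000728), while its gene, with 6 isoforms, rose by a log2 fold change of 0.51. TRINITY_DN2859_c0_g1_i13 rose from 0 to 4.95 ± 2.41 CPM, at least 49.6-fold (24.9-fold without stage 2 replicate 1; edgeR, adjusted p = 0.0417), and its gene rose by 0.53. That call was lost under 17 of 26 alternatives with adjusted p up to 0.134, among them leaving out stage 1 replicate 1, stage 4 replicate 1 or 3, or any library of stages 2, 3 and M (0.0525 to 0.134). The fit with the replicate number as a block also lost it (edgeR, adjusted p = 0.0597). TRINITY_DN3991_c0_g1_i1 fell from 161 ± 112 to 1.42 ± 1.68 CPM (log2 fold change -6.72, SE 0.84; edgeR, adjusted p = 0.00338) and TRINITY_DN24639_c0_g1_i2 from 43.6 ± 15.6 to 1.04 ± 0.923 CPM (log2 fold change -5.36, SE 0.59; edgeR, adjusted p = 0.000947). Without stage 2 replicate 2 or stage 3 replicate 1 the log2 fold change of TRINITY_DN3991_c0_g1_i1 was -6.02 or -8.35. Its gene had a log2 fold change of 0.18 that did not pass (edgeR, adjusted p = 0.830), and the gene of TRINITY_DN24639_c0_g1_i2 rose by 0.61 (edgeR, adjusted p = 0.0201). The count of 1447 was 461 or 711 without stage 2 replicate 2 or 3 and 560 or 791 without stage 3 replicate 2 or 3. It was 3389 with DESeq2, of which 46.4% rose against 56.9%, 483 in a test against a 1.5-fold change, of which 232 rose and 251 fell, and 2232 for summed genes.

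The step from stage 3 to stage 4 had the most changes of the 4 consecutive steps, and more transcripts fell than rose. Of 5944 transcripts that passed (19.1%), 2372 rose and 3572 fell, with median log2 fold changes of 1.23 and -2.22 (-2.03 with bounds), and of those that changed at least 4-fold 446 rose and 1946 fell. Leaf-preferring transcripts went against that majority: 1328 rose, 155 fell and 2171 did not pass (median 0.84 with and without bounds; camera, adjusted p = 4.2e-30, and 0.00195 with an estimated correlation). Among the root-preferring transcripts 32 rose, 665 fell and 2632 did not pass (median -0.79, -0.69 with bounds; camera, adjusted p = 1.41e-06, and 0.00561 with an estimated correlation). TRINITY_DN1634_c0_g4_i1 rose from 0.753 ± 0.738 to 132 ± 138 CPM (SD, n = 3; log2 fold change 7.52, SE 0.99; edgeR, adjusted p = 0.000226) and TRINITY_DN19258_c0_g1_i4 from 0.561 ± 0.348 to 30.4 ± 18.7 CPM (log2 fold change 5.69, SE 0.55; edgeR, adjusted p = 2.7e-05), both with a single isoform in the data. Without stage 4 replicate 2 these log2 fold changes were 6.20 and 5.02, and without stage 3 replicate 3 the former was 8.57. TRINITY_DN997_c0_g2_i1 fell from 142 ± 3.92 CPM to 0, at least 269-fold (165-fold or 163-fold without stage 4 replicate 1 or 2; edgeR, adjusted p = 4.9e-07), and its gene by a log2 fold change of -6.37. TRINITY_DN4692_c1_g1_i11 fell from 170 ± 13.2 CPM to 0, at least 324-fold (198-fold or 197-fold without these in turn; edgeR, adjusted p = 4.57e-07), while its gene had a log2 fold change of 0.27 that did not pass (edgeR, adjusted p = 0.114). Stage 4 had the lowest depth, and 520 of the transcripts that passed were at 0 in all libraries of a group. The count was 3234 in a fit of these 2 stages alone and 3318 in a test against a 1.5-fold change.

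From stage 4 to stage M, about as many leaf-preferring transcripts rose as fell. Among all transcripts falls outnumbered rises in the fit of all 15 libraries, but not in a fit of these 2 stages alone. Stage 4 libraries correlated with stage M libraries (mean r = 0.780) about as well as with each other (mean r = 0.790). The CPM ranges of the 2 groups did not overlap for 6001 transcripts (19.3%, against 10% by chance). Of 2456 transcripts that passed (7.91%), 812 rose and 1644 fell, with median log2 fold changes of 1.15 and -2.74 (-2.43 with bounds). Among the leaf-preferring transcripts 187 rose, 167 fell and 3300 did not pass (median 0.22 with and without bounds; camera, adjusted p = 0.000359), a call that was lost with an estimated correlation (adjusted p = 0.258). Among the root-preferring transcripts 47 rose, 288 fell and 2994 did not pass (median -0.49, -0.65 with bounds; camera, adjusted p = 0.00106), and this call too was lost with an estimated correlation (adjusted p = 0.103). TRINITY_DN24639_c0_g1_i2 rose from 0 to 147 ± 29.0 CPM (SD, n = 3), at least 283-fold (173-fold or 172-fold without stage 4 replicate 1 or 2; edgeR, adjusted p = 0.000340). TRINITY_DN2443_c0_g1_i15 rose from 0 to 31.5 ± 1.69 CPM, at least 60.2-fold (36.8-fold or 36.5-fold without these in turn; edgeR, adjusted p = 0.00530). Their genes had log2 fold changes of -0.03 and 0.51 that did not pass (edgeR, adjusted p = 0.959 and 0.263). TRINITY_DN603_c0_g1_i22 fell from 46.8 ± 36.9 CPM to 0, at least 109-fold (69.3-fold without stage M replicate 1; edgeR, adjusted p = 0.0247). TRINITY_DN1418_c0_g1_i21 fell from 32.0 ± 41.1 CPM to 0, at least 48.2-fold (16.8-fold without stage 4 replicate 3 and 30.6-fold without stage M replicate 1; edgeR, adjusted p = 0.0385). The gene of the former had a log2 fold change of -0.20 that did not pass (edgeR, adjusted p = 0.270), and the gene of the latter fell by a log2 fold change of -4.32. The call of TRINITY_DN603_c0_g1_i22 was lost under 6 of 26 alternatives (edgeR, adjusted p up to 0.0762), among them leaving out stage 4 replicate 1 or any stage M library (0.0590 to 0.0734). The call of TRINITY_DN1418_c0_g1_i21 was lost under 12 of 26 (edgeR, adjusted p up to 0.118), among them leaving out stage 1 replicate 3, stage 2 replicate 2 or 3, stage 3 replicate 3, stage 4 replicate 1 or 3 or any stage M library (0.0502 to 0.107). The count of 2456 was 1467 without stage 4 replicate 1 and 1435 without stage M replicate 1. It was 4163 with DESeq2, 1182 in a test against a 1.5-fold change and 56 in a fit of these 2 stages alone, of which 32 rose and 24 fell.

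Between the ends of the numbered series, stages 1 and 4, the leaf-preferring list rose and the root-preferring list fell. Of the leaf-preferring transcripts 2260 (61.9%) rose and 173 (4.73%) fell, where 16.9% of all tested transcripts rose and 21.8% fell; their median log2 fold change was 1.74 with and without bounds (camera, adjusted p = 5.48e-44, and 0.000291 with an estimated correlation). Of the root-preferring transcripts 144 (4.33%) rose and 1241 (37.3%) fell, with a median of -1.38 (-1.26 with bounds; camera, adjusted p = 1.78e-09, and 0.00135 with an estimated correlation). In all, 12014 transcripts passed (38.7%), of which 5253 rose and 6761 fell, and 6956 changed at least 4-fold, 2764 upward and 4192 downward. The median log2 fold change of all tested transcripts was -0.29. The CPM ranges of the 2 groups did not overlap for 15764 transcripts (50.7%, against 10% by chance). TRINITY_DN1816_c0_g1_i11 rose from 0 to 178 ± 23.8 CPM (SD, n = 3), at least 1409-fold (896-fold or 909-fold without stage 1 replicate 2 or 3; edgeR, adjusted p = 5.48e-08). TRINITY_DN2747_c0_g1_i11 rose from 0 to 150.02 ± 78.5 CPM, at least 1291-fold (821-fold or 833-fold without these in turn; edgeR, adjusted p = 2.24e-06). Their genes rose by log2 fold changes of 3.75 and 5.14. TRINITY_DN3991_c0_g1_i1 fell from 426 ± 39.2 CPM to 0, at least 818-fold (501-fold or 496-fold without stage 4 replicate 1 or 2; edgeR, adjusted p = 7.2e-05). TRINITY_DN4692_c1_g1_i11 fell from 182 ± 22.9 CPM to 0, at least 350-fold (214-fold or 212-fold without these in turn; edgeR, adjusted p = 6.47e-08). The genes of these 2 that fell had log2 fold changes of -0.57 and 0.13 that did not pass (edgeR, adjusted p = 0.197 and 0.396). Of the 12014 transcripts, 10725 belonged to a gene whose summed count passed in the same direction and 224 to one that passed in the opposite direction. The summed count holds the transcript itself, and equals it where the gene has a single isoform, so part of this match is built in.

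**Figure D2:**
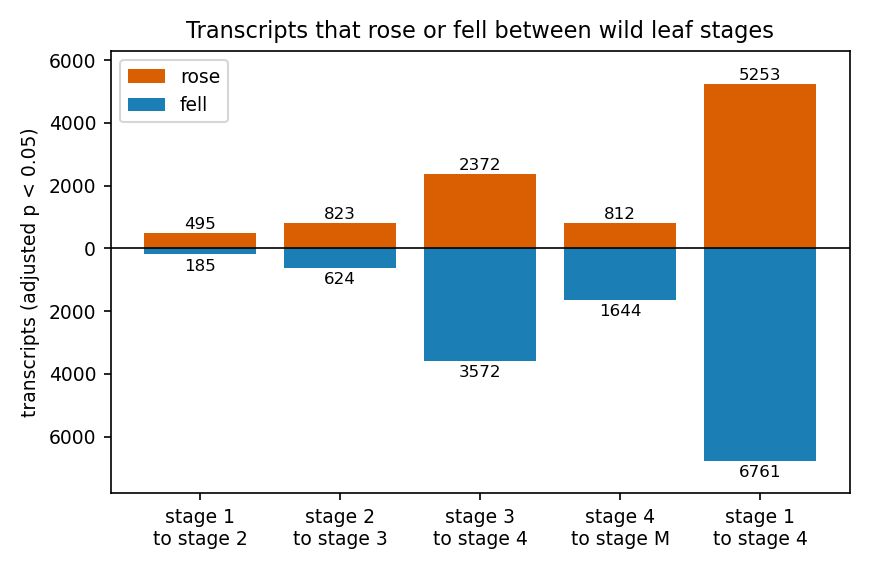
Transcripts that rose (upward bars) or fell (downward bars) between wild leaf stages at an edgeR adjusted p under 0.05; the vertical axis counts transcripts in both directions from 0. The step from stage 1 to stage 2 has 495 rises and 185 falls, and that from stage 3 to stage 4 has 2372 rises and 3572 falls.

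**Figure D3:**
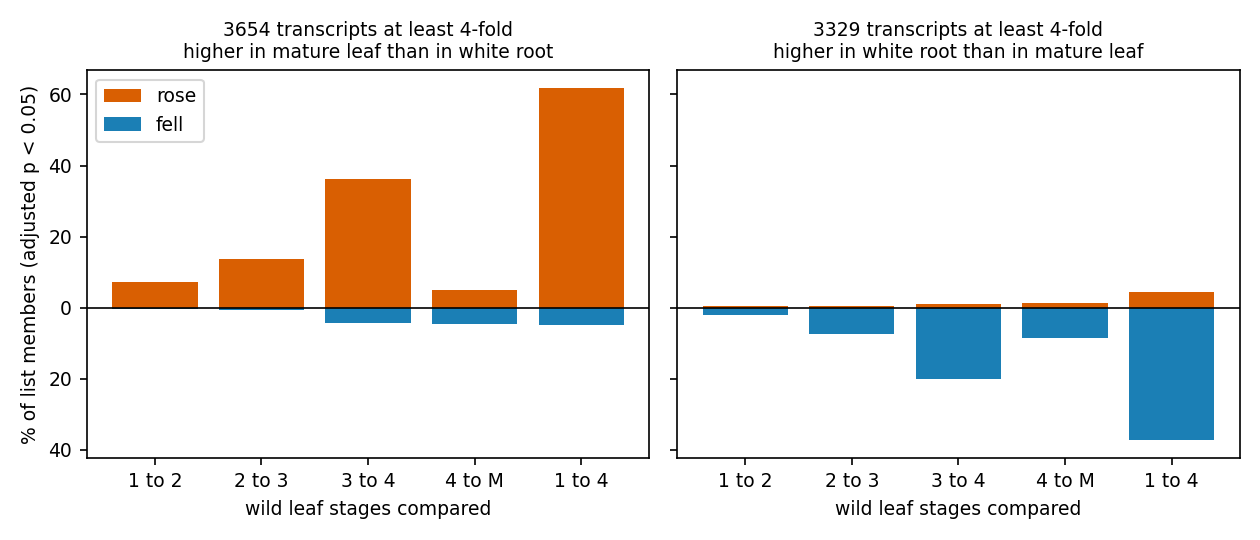
Share of leaf-preferring (left, 3654 transcripts) and root-preferring (right, 3329 transcripts) list members that rose (upward bars) or fell (downward bars) between wild leaf stages; the vertical axis gives percent of list members. From stage 1 to stage 4, 61.9% of the former rose and 37.3% of the latter fell.

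A few transcripts took a growing share of the counts over the wild leaf stages. The 3 most abundant at stage M, singled out after their values were seen, were TRINITY_DN307550_c0_g1_i1, TRINITY_DN482036_c0_g1_i1 and TRINITY_DN147260_c0_g1_i1, each with a single isoform in the data. Together they held 1.01 ± 0.207% of the counts at stage 1, 1.97 ± 0.453% at stage 2, 4.90 ± 0.607% at stage 3, 17.9 ± 2.46% at stage 4 and 33.3 ± 7.16% at stage M (SD, n = 3). At stage M they held 14.1 ± 3.53%, 12.9 ± 2.20% and 6.25 ± 1.43%, in the order named, from 0.394 ± 0.0910%, 0.424 ± 0.0784% and 0.193 ± 0.0387% at stage 1. Hydroponic mature leaves had 0.660 to 1.77% in the 3 together and roots at most 0.0287%. The transcripts that held 50% of the counts numbered 2059 ± 66.5 at stage 1, 276 ± 85.0 at stage 4 and 79 ± 71.1 at stage M. The stage M mean was raised by replicate 3, with 161, where replicates 1 and 2 had 41 and 35. With all libraries thinned to one total, the abundant transcripts included, 24473 ± 480 transcripts had at least 5 counts at stage 1, 17857 ± 879 at stage 4 and 15253 ± 1070 at stage M. With the 20 most abundant at stage M taken out before thinning, the numbers were 22511 ± 323, 17851 ± 719.9 and 16489.7 ± 515, and the stage M mean was 73.3% of that at stage 1. In the exact two-sided permutation test of stage 1 against stage M each of these measures had p = 0.1, the smallest that 3 against 3 libraries allow. The 3 transcripts were chosen for their abundance at stage M, so for their share this p carries no support. The permutations also took no account of the replicate numbers, which were taken to pair the samples. Swaps within pairs alone would leave a larger smallest p.

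**Figure D4:**
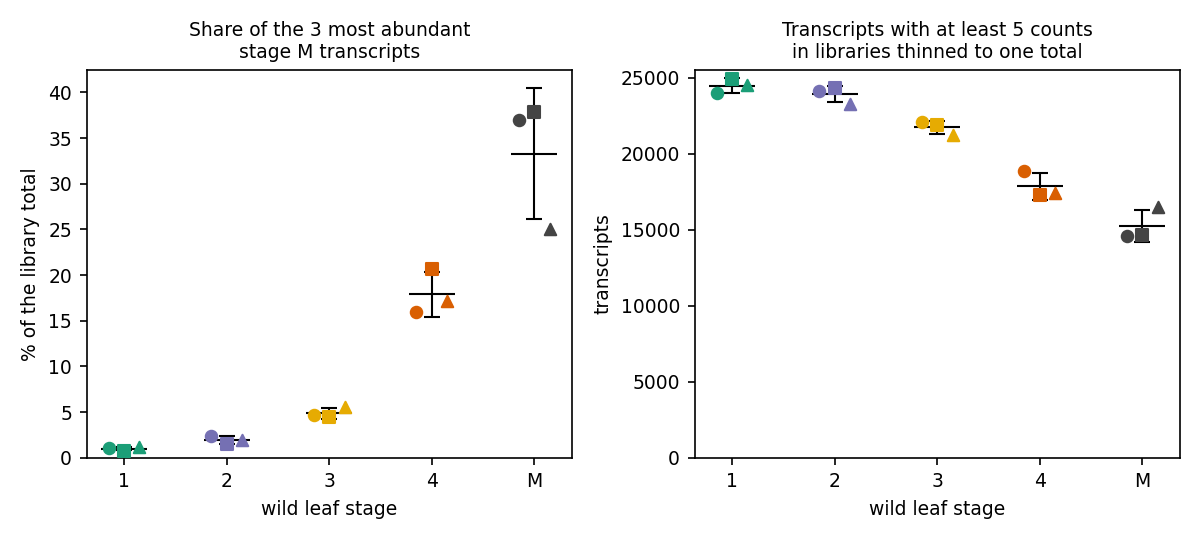
Left, percent of the library total in the 3 most abundant stage M transcripts; right, number of transcripts with at least 5 counts when all libraries are thinned to one total; both by wild leaf stage, with points for replicates and bars for mean ± SD. The share rises from 1.01% at stage 1 to 33.3% at stage M and the number of transcripts falls from 24473 to 15253, with the abundant transcripts counted in the total.

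White roots and mature leaves in hydroponics differed in 12752 of 36407 tested transcripts (35.0%; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), 7007 higher in root and 5745 higher in leaf. Of these, 5715 were at least 4-fold higher in root and 3963 in leaf, and 9892 of 19418 summed genes differed. TRINITY_DN185839_c0_g1_i1 was at 862 ± 143 CPM in white root (SD over 3 Pi levels) and at 0 in mature leaf, at least 12525-fold higher in root (8241-fold or 8258-fold without the leaf library at 1 or 50 uM Pi; edgeR, adjusted p = 0.00133). TRINITY_DN1703_c0_g1_i18 was at 729 ± 376 CPM in root and at 0 in leaf (edgeR, adjusted p = 0.00393). TRINITY_DN850_c0_g1_i13 held 49704 ± 3946 CPM in mature leaf against 2 counts in the 3 root libraries, a ratio of 982842 with a 95% counting interval of 272078 to 8115650 (edgeR, adjusted p = 0.000930). The ratio was 612703 without the root library at 1 uM Pi and at least 461514 without that at 50 uM, which held both counts. TRINITY_DN3177_c0_g1_i21 was at 4140 ± 843 CPM in leaf and at 0 in root, at least 54616-fold higher in leaf (34048-fold without the root library at 1 uM Pi; edgeR, adjusted p = 0.00133). The genes of the last 2 had log2 fold changes of root over leaf of -10.56 and -7.75. The median log2 fold change of root over leaf across all tested transcripts was 0.46. With 1 library per tissue and Pi level, the spread in this test is departure from a common log-linear Pi trend with 3 residual degrees of freedom. The count was 8101, 5307 or 5854 without the white root library at 1, 10 or 50 uM Pi, each with more transcripts higher in leaf than in root (4558 against 3543, 3343 against 1964 and 3410 against 2444), 7487 or 7675 without the mature leaf library at 1 or 10 uM Pi, 7114 with Pi as a 3-level factor (3026 higher in root and 4088 in leaf) and 19233 with DESeq2.

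No transcript passed the test for a trend with Pi supply shared by white root and mature leaf. At an adjusted p under 0.05 edgeR called 0 of 36407 transcripts, with 1569 at an unadjusted p under 0.05 and a lowest adjusted p of 0.947, and DESeq2 called 345, 166 of them higher and 179 lower with more Pi. The Pi slope differed between white root and mature leaf for 0 transcripts in edgeR, with 4215 at an unadjusted p under 0.05 and a lowest adjusted p of 0.397. With no true effect, a share of about 0.05 of the 36407 transcripts would have such an unadjusted p. The 1569 of the shared trend lie below that share and the 4215 of the slope difference above it. Slopes that differ between the tissues therefore stay open, and they would add to the spread in the fit of a shared trend. Between single libraries, with no replicate check, mature leaf at 50 uM Pi was at least 4-fold apart from mature leaf at 1 uM for 3292 of 19772 transcripts (16.6%), 1784 higher and 1508 lower. White root at 50 uM was as far from white root at 1 uM for 1182 of 19632 (6.02%), 424 higher and 758 lower. From 1 to 10 uM the numbers were 1376 of 19895 in white root (6.92%; 461 higher and 915 lower) and 1211 of 18653 in mature leaf (6.49%; 541 and 670). From 10 to 50 uM they were 430 of 17859 in white root (2.41%; 250 and 180) and 2168 of 18987 in mature leaf (11.4%; 1318 and 850). Pairs of wild leaf replicates differed as much in 1.63 to 3.29% of transcripts at stages 1 to 3, up to 5.32% at stage 4 and up to 2.24% at stage M. These replicates grew in the field and had other depths, so they are only a rough measure for hydroponic libraries.

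More cluster root transcripts were far from their day 0 level on each later day, and by day 12 more were lower than higher. Against day 0, 308 transcripts were at least 4-fold different on day 1 (219 higher and 89 lower), 861 on day 4 (637 and 224), 2549 on day 7 (1488 and 1061) and 5835 on day 12 (2439 and 3396). These were 1.77%, 4.91%, 13.8% and 31.2% of the transcripts with at least 100 counts in a library of the pair. Pairs of wild leaf replicates differed as much in 1.38 to 5.32%, a range that includes the values of days 1 and 4. For day 4 this rests on the pairs with stage 4 replicate 2, at 5.07% and 5.32%. The other pairs were at most at 3.29%, below the value of day 4, and pairs of stages 1 to 3 were at 1.63 to 3.29%. These pairs are field leaves and differ from the cluster roots in organ, growth setting and depth. They had 3907 to 16129 transcripts past the minimum of 100 counts, against 17434 to 18673 for the cluster root days. The range is therefore only a rough measure for cluster roots. The consecutive steps, which span unequal times, held 308 such differences from day 0 to 1, 160 from day 1 to 4, 461 from day 4 to 7 and 1706 (545 higher and 1161 lower) from day 7 to 12. The 2439 transcripts higher on day 12 had median log2 differences from day 0 of 0.74, 0.98, 2.10 and 3.12 on days 1, 4, 7 and 12, and the 3396 lower ones of -0.50, -0.64, -1.39 and -3.28. A further 254 transcripts were at least 4-fold higher on a day between than on both day 0 and day 12, with the highest value on day 1 for 23, day 4 for 96 and day 7 for 135. Another 29 were at least 4-fold lower on a day between than on both. TRINITY_DN6504_c0_g1_i15 went from 0 counts on day 0 to 2309 CPM on day 12 (95% interval 2274 to 2343), at least 9021-fold higher. TRINITY_DN1294_c1_g1_i2 went from 3 counts to 5202 CPM (5150 to 5254), a ratio of 20325 with a counting interval of 6954 to 98562. TRINITY_DN3199_c0_g1_i7 went from 457 CPM (445 to 469) to 0, at least 1136-fold lower, while the log2 difference of its gene, with 8 isoforms, was -1.12. TRINITY_DN21323_c0_g1_i13 went from 684 CPM (670 to 700) to 2 counts, a ratio of 2553 with a counting interval of 706 to 21083. Each day had 1 library, so these differences had no replicate check and the exact Poisson and binomial intervals cover counting error only. With library totals in place of TMM the median log2 difference of all transcripts moved from -0.03 to -0.17 on day 4, from -0.03 to -0.21 on day 7 and from -0.16 to -0.40 on day 12, and the day 7 split turned to 1282 higher and 1304 lower.

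**Figure D5:**
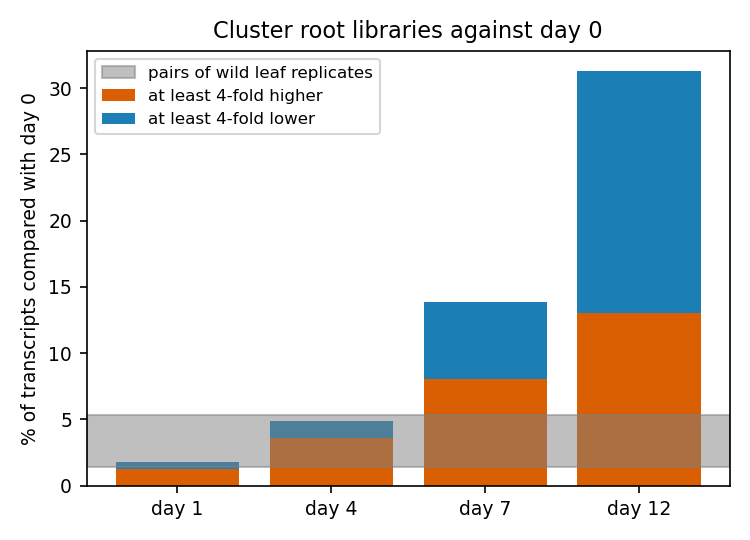
Percent of transcripts at least 4-fold higher (lower part of each bar) or lower (upper part) in cluster roots on days 1, 4, 7 and 12 than on day 0, with 1 library per day. The grey band, 1.38 to 5.32%, is the range over 15 pairs of wild leaf replicates, which differ from the cluster roots in organ, growth setting and depth. The bars of days 1 and 4 end within it, at 1.77% and 4.91%, and the bar of day 12 stands at 31.2%. Only the pairs with stage 4 replicate 2, at 5.07% and 5.32%, lie above day 4, and the other pairs reach at most 3.29%.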

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

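Counts summed per Trinity gene, thinned libraries, the block without stage 4 replicate 3 and the alternatives for lists were added after the data had been seen, and the other alternatives were set in advance. The counts over the 5 wild leaf groups and from stage 1 to stage 4 stayed within 1.5 times their values under every alternative run. DESeq2 gave 2405, 3389 and 4163 transcripts for stages 1 to 2, 2 to 3 and 4 to M, 19233 for tissue and 345 for Pi. Fits of 2 stages alone gave 1891, 3234 and 56 for stages 1 to 2, 3 to 4 and 4 to M. A test against a 1.5-fold change gave 207, 483, 3318 and 1182 for the 4 consecutive steps, fewer by construction, and summed genes gave 1484 and 2232 for the first 2 steps. The replicate block gave 1092 for stages 1 to 2, and 1109 without stage 4 replicate 3; it changed no other count by over 1.5 times, no list call and, of the named transcripts, only the call of TRINITY_DN2859_c0_g1_i13 for stages 2 to 3 (edgeR, adjusted p = 0.0597, and 0.0645 without stage 4 replicate 3). Pi as a factor gave 7114 for tissue. A minimum of 20 counts gave 1619, 2737, 5409 and 10272 cluster root transcripts on days 1, 4, 7 and 12, since more transcripts entered. For DESeq2, the fits of 2 stages, the block and Pi as a factor the cause was not tested.

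With 1 library left out in turn, the counts ranged from 189 to 1120 for stages 1 to 2, 461 to 2034 for stages 2 to 3, 4174 to 6170 for stages 3 to 4, 1435 to 3656 for stages 4 to M, 10127 to 12252 for stages 1 to 4, 12669 to 14503 over the 5 groups and 5307 to 10272 for tissue, and the Pi count stayed at 0. Leaving out a library left its stage with 2, and in the hydroponic fits with 2 residual degrees of freedom. Of 564 alternatives over 24 named results, 529 kept the direction and the threshold, 35 kept the direction only and 0 reversed. The named transcripts were chosen for large changes and ranges that do not overlap in these libraries, so a reversal was unlikely from the start. Of the list calls, those for stages 4 to M were lost with an estimated correlation, where leaf-preferring transcripts had an adjusted p of 0.258 and root-preferring ones 0.103. The separate question of fry, whether a list moved on balance, had an adjusted p of 0.0956 for leaf-preferring transcripts from stage 4 to M. The alternatives fixed for the 24 gene lists could not be run, since these lists matched no ID. With all 15 wild leaf libraries thinned to the lowest total, the counts were 633, 1293, 5312, 1811 and 10413 for the contrasts in the order of the report and 12083 over the 5 groups.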

Other observations

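The lists below, the tests on the 3 abundant transcripts, the comparison of values that are not whole and the regroupings within replicate numbers were chosen after the results had been seen. Transcripts at least 4-fold different between day 0 and day 12 in cluster roots also changed over the wild leaf stages. Of 3120 tested transcripts lower on day 12, 2002 (64.2%) fell and 185 (5.93%) rose from stage 1 to stage 4 (median log2 fold change -2.19, -2.17 with bounds; camera, adjusted p = 1.4e-24, and 0.000269 with an estimated correlation). They also fell more often than they rose from stage 1 to 2 (117 against 43; camera, adjusted p = 4.13e-14), from 2 to 3 (425 against 42; camera, adjusted p = 1.99e-18) and from 3 to 4 (1057 against 110; camera, adjusted p = 6.76e-13), while the list did not pass from 4 to M (282 against 111; camera, adjusted p = 0.527). Of 1567 transcripts higher on day 12, 548 rose and 162 fell from stage 1 to stage 4 (median 0.65, 0.66 with bounds; camera, adjusted p = 3.3e-08, and 0.00447 with an estimated correlation), and from 3 to 4 221 rose and 99 fell (camera, adjusted p = 0.000608, and 0.0471 with an estimated correlation). For that step fry, which asks whether a list moved on balance and not whether it differed from other transcripts, gave an adjusted p of 0.185. From 1 to 2, 56 of them rose and 3 fell (camera, adjusted p = 1.64e-05), from 2 to 3, 113 rose and 11 fell (camera, adjusted p = 4.21e-06), and from 4 to M the list did not pass (68 against 89; camera, adjusted p = 0.0949). The camera calls of both lists that passed also held with an estimated correlation. The list lower on day 12 shares 936 transcripts with the root-preferring list and 162 with the leaf-preferring list.

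The fall of that list in leaves was weighed against low counts in the later libraries. Its 569 members with a mean log2 CPM of at least 5 had a median log2 fold change of -1.23 from stage 1 to stage 4, where all transcripts of that abundance had 0.27 and 10000 random lists matched on mean expression gave 0.17 to 0.42, which argues against low counts as the whole cause. The median of the full list, -2.19, lay below the range of matched random lists, -0.27 to -0.15. That restates the fall of the list and cannot tell whether its transcripts are lower in older tissue of both organs. Across 16969 transcripts, which are not independent, the change in cluster roots and that in leaves had a Spearman rho of 0.471, and each cluster root day has 1 library, so age and any other difference between these libraries stay open.

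The growing share of 3 transcripts was set beside the library totals. A share is a percent of the total, so drawing fewer reads from the same RNA would not by itself raise it. The comparison is therefore no test of depth itself, only of differences that came with lower totals. The mean share rose 4.84 times from stage 1 to stage 3 with totals that overlapped. It rose 1.86 times from stage 4 to stage M with a mean total 1.41 times higher. The shares did not overlap in either pair of groups. From stage 3 to stage 4 the mean share rose 3.66 times while the mean total fell to 0.440 of that at stage 3. Stage and any other difference that came with the lower totals cannot be told apart for that rise. Over the 15 wild leaf libraries the largest SD of a log2 ratio between 2 of the 3 transcripts was 0.144, so a candidate source is one kind of RNA that carries all 3 in a fixed ratio. In hydroponic mature leaf the ratio was another, with 0.0306 to 0.0883% in TRINITY_DN147260_c0_g1_i1 and 0.344 to 0.891% in TRINITY_DN307550_c0_g1_i1, where wild leaf at stage M had 6.25% and 14.1%. What this RNA is was not tested, and a change with leaf stage, with RNA preparation or with the removal of ribosomal RNA stays open.

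Some transcripts switched while their gene did not. Of the 6956 transcripts that changed at least 4-fold from stage 1 to stage 4, 363 (5.22%) belonged to a gene whose log2 fold change was under 0.5 in size, and for 144 of these (39.7%) another isoform of the gene passed in the opposite direction. In the median such transcript 100% of the values above 0 were not whole. The median was also 100% for the 3484 transcripts whose gene had several isoforms and changed at least 4-fold in the same direction, so this measure cannot separate the switches from other transcripts of such genes. Reads shared between near-identical isoforms and a change in isoform use with leaf stage both stay open.

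Other splits of the same libraries were counted. For each contrast, 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05, and 1 split, the real one, gave as many transcripts. The highest counts of the other splits were 0 for stages 1 to 2 (real 680), 1 for 2 to 3 (real 1447), 0 for 3 to 4 (real 5944), 150 for 4 to M (real 2456), 0 for 1 to 4 (real 12014) and 0 for tissue in hydroponics (real 12752). Of the 4 splits of a wild leaf contrast that part all 3 same-numbered pairs as the real one does, the highest other counts were 0, 0, 0, 9 and 0, and the count of 150 came from a split that parts 1 pair. Over the 5 wild leaf groups 1 of 24 regroupings, the real one, gave as many as 14224, and the highest other gave 791. With stages permuted within each replicate number, 1 of 50 regroupings, the real one, gave as many, and the highest other gave 617. Both shares are under 0.05 and are the smallest that 24 and 50 regroupings allow, so they say only that no other regrouping drawn gave as many. The number of 24 was set after a larger draw with the same seed had been seen. Regrouped libraries carry the differences between stages as spread, which lowers their counts. A difference in depth or any other that goes with the groups would also set the real grouping apart.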
